A study of Homo sapiens with 24 samples.

How the data were processed

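RNA from wt, OHT-resistant and ICI-resistant MCF7 cells, each kept in DMSO or estradiol, was measured on 24 one-colour Affymetrix HG-U133 Plus 2 arrays, 4 per group. The deposited intensities are whole numbers on a linear scale, 1 summarised value per probe set, and the trimmed mean (2% at each end) of every array was 1000.2, so each array appears scaled as a whole. The summarising algorithm, its version and the scaling that the authors used are not stated in the sources used here. The largest intensity was 140660. The number of arrays limits the precision. The design text calls the wt replicates biologically independent and says nothing of this kind about the other lines.

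The quartiles of the arrays differed by 0.36, 0.43 and 0.37 on the log2 scale, more than the 0.05 set as the limit for using the values as they are. The values were therefore taken to log2 after adding 21, the 10th percentile of all values, and quantile normalized. Probe sets above the median of their own array on at least 4 of 24 arrays were kept, which left 34580. Of all probe sets 41097 had 1 gene symbol, 1801 had several and 11777 had none given, and the latter kinds were left out. Each of 14689 genes was represented by its probe set of highest mean over all arrays, preferring those whose name does not end in _x_at, which stood for 445 genes, and 7106 genes had more than 1 kept probe set. No genome build or coordinates came with the series, so genes are given by symbol. There were 0 pairs of arrays with identical values.

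Group means were fitted over all 24 arrays with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3. The 9 contrasts were estradiol against DMSO in each line, each pair of lines in DMSO, and the differences of the estradiol responses between lines. Adjusted p-values are Benjamini-Hochberg over the genes tested, with 0.05 as the threshold. The test is the moderated test of limma and was two-sided. A set of 25 gene lists, with 524 entries of which 438 were tested, was tested with camera at a preset correlation of 0.01, adjusted over the 25 lists of each comparison, and calls that ended with an estimated correlation have that adjusted p beside them. Control probe sets were compared by exact two-sided permutation tests.

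The groups, contrasts, tests, gene lists and alternatives were set before the data were examined, as was the rule for named genes. That rule names, per comparison, the 8 largest increases and the 8 largest decreases among called genes whose groups do not overlap (for differences of responses, among called genes), up to 4 members of smallest adjusted p from each list described, and ESR1, PGR, TFF1, GREB1, EGFR and ERBB2. Members that went against the direction of their list were named after their values were seen. Alternatives were the values as deposited, median centring, other pseudocounts (5.25 and 84), no filter and a stricter one, the mean of the probe sets of a gene, eBayes without the trend, only the arrays compared, the replicate number as a block, a log2 fold change of at least 1, and leaving out each array in turn. A batch term, the removal of 4 arrays, a term for the code letter of the wt arrays and the removal of the 2 with another letter were added after the data had been seen.

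The procedure was tested on simulated data of the same size and spread. In the first of these, changes of 0.5, 1, 2 and 4 on the log2 scale were recovered in 38%, 60%, 90% and 100% of genes for estradiol in wt cells. Unchanged genes made up 6.79% of calls (1.9% to 9.77% over 10 draws) for estradiol in wt cells, 8.44% (5.56% to 12.9%) for OHT-resistant against wt cells, and 5.18% (3.91% to 6.69%) for the difference of the ICI-resistant and wt responses. Without the quantile step these shares were 4.79%, 5.71% and 4.81%. Of 25 simulated lists the changed 1 was called, and 0 of the others were. The simulated genes were drawn independently of each other, so list calls among correlated genes were not tested. Far fewer genes were changed than were called in the real comparisons, so the shares of unchanged genes may not carry over.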

Results

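Gene expression was measured in MCF7 cells, an established line from an estrogen receptor-positive breast cancer that depends on estrogen for growth. There were 3 lines: wild-type (wt) cells and lines that the labels call OHT-resistant and ICI-resistant, names that in this field usually refer to antiestrogens. Cells of each line received the solvent DMSO or 17β-estradiol, the main natural estrogen, for 4 h. The labels give an estradiol concentration of 10 nM for the wt and OHT-resistant arrays but only an amount of 1 unit for the ICI-resistant ones, so whether the dose was the same is not known. Each of the 6 groups held 4 arrays, 24 in all, and the number of arrays limits the precision. Each kind of resistance is represented by 1 line, so p-values between lines measure the spread among arrays and not among resistant lines. The design text calls the wt replicates biologically independent and says nothing of this kind about the other lines. After a filter on dim probe sets 34580 were kept, and 14689 genes were tested. Unless stated otherwise, values below are log2 fold changes ± SE from 4 against 4 arrays, with adjusted p-values from limma. Where a gene lies near background in a group, the size of its log2 fold change depends on the 21 added to each value and is not a measured fold.

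The genes known to mark estrogen receptor action were examined first, since they check the labels. ESR1, which encodes estrogen receptor alpha, had a deposited intensity of 25950 ± 1650 (SD, n = 4) in wt cells in DMSO, 11840 ± 940 (SD, n = 4) in the OHT-resistant line and 1002 ± 120 (SD, n = 4) in the ICI-resistant line. Relative to wt these were log2 fold changes of −1.08 ± 0.09 (adjusted p = 1.83e-10) and −4.80 ± 0.09 (adjusted p = 9.67e-25). Of the 5 ESR1 probe sets 2 were called lower in each of these comparisons and 0 higher. PGR, the progesterone receptor gene and a classical estrogen target, stood at 402 ± 32.8 in wt cells in DMSO and at 5556 ± 590 with estradiol (SD, n = 4). In the OHT-resistant line it went from 122.5 ± 22.9 to 299.2 ± 47.9, and in the ICI-resistant line it was 61.5 ± 49.7 and 58.75 ± 48.9 (SD, n = 4). GREB1, an estrogen-induced growth regulator, had an intensity of 11520 ± 1110 in wt cells in DMSO, 117.8 ± 41.3 in the OHT-resistant line and 193.5 ± 38.4 in the ICI-resistant line (SD, n = 4). TFF1, a secreted trefoil peptide gene, was among the brightest genes in wt cells (79180 ± 5580; SD, n = 4) and in the OHT-resistant line (99820 ± 5440; SD, n = 4). It was lower in the ICI-resistant line (10470 ± 1220; SD, n = 4).

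**Figure D1:**
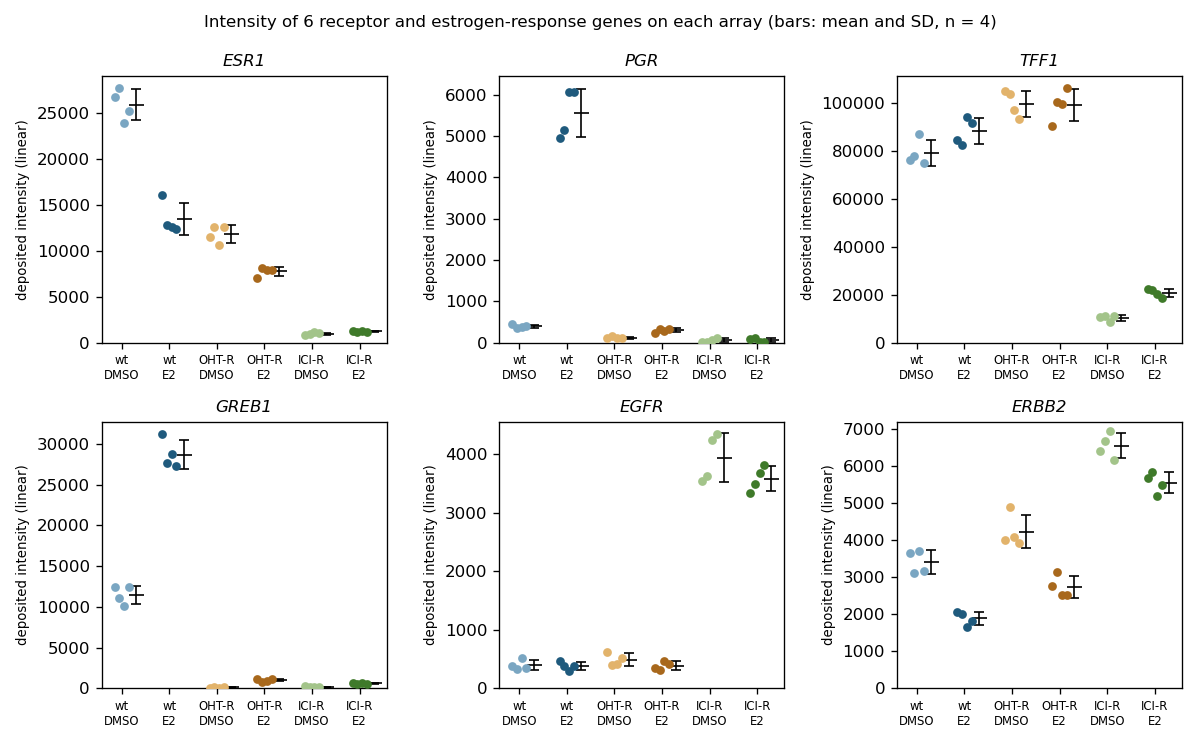
Deposited intensity on a linear axis (vertical) of ESR1, PGR, TFF1, GREB1, EGFR and ERBB2 on each of the 24 arrays (points), by line and treatment (horizontal), with the mean and SD of the 4 arrays of a group (bars). ESR1 falls from 25950 in wt DMSO to 1002 in ICI-resistant DMSO, and PGR with estradiol reaches 5556 in wt and 299.2 in OHT-resistant cells.

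In wt cells estradiol raised known estrogen targets together with genes of DNA replication and ribosome production. The largest log2 fold changes upwards were in SMTNL2 (4.83 ± 0.44), RAPGEFL1 (4.49 ± 0.32), PGR (3.50 ± 0.36), TUBB2B (3.37 ± 0.42), CHST8 (3.33 ± 0.41), TFF2 (3.29 ± 0.43), TGM2 (3.26 ± 0.37) and SCNN1G (3.25 ± 0.51). The largest decreases were in GTF2IP20 (−3.16 ± 0.51), MMP13 (−2.94 ± 0.43), CHRM1 (−2.87 ± 0.54), GRHL3 (−2.59 ± 0.39), WNT7B (−2.49 ± 0.34), SOX2 (−2.46 ± 0.16), ZNF792 (−2.27 ± 0.47) and TM4SF1 (−2.22 ± 0.15). The adjusted p of these 16 genes was at most 0.000661. ESR1 itself fell by 0.96 ± 0.09 on the log2 scale (adjusted p = 5.93e-09), although only 1 of its 5 probe sets was called. ERBB2 fell as well (−0.78 ± 0.08, adjusted p = 3.31e-08) and GREB1 rose (1.27 ± 0.16, adjusted p = 8.48e-07). Neither TFF1 (0.10 ± 0.08, adjusted p = 0.43) nor EGFR (−0.07 ± 0.16, adjusted p = 0.824) passed the threshold.

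In all, 3141 of 14689 genes changed in wt cells, 1416 upwards and 1725 downwards. When each array was centred on its median instead of quantile normalized, 1008 were higher and 2344 lower, so the share of increases fell from 45.1% to 30.1%, while 253 rose and 233 fell by a log2 fold change of at least 1. Of 35 estrogen-induced targets tested, 32 rose and 1 fell (camera adjusted p = 3.44e-43), and 33 were called when adjusted over the list alone. CA12, a carbonic anhydrase (2.40 ± 0.07), the amino acid transporter gene SLC7A5 (2.28 ± 0.07), the receptor tyrosine kinase gene RET (2.94 ± 0.12) and IGFBP4 (2.75 ± 0.13) were the clearest, while AMIGO2 went the other way (−1.40 ± 0.10). Of 16 estrogen-repressed genes, 12 fell and 0 rose (adjusted p = 4.88e-13; 13 adjusted over the list alone). Examples were the stress-response gene TP53INP1 (−1.88 ± 0.09), the atypical cyclin gene CCNG2 (−1.42 ± 0.12) and TGFB2 (−1.61 ± 0.16). DNA replication genes rose in 24 of 28 cases (adjusted p = 1.54e-20; 24 adjusted over the list alone). Examples were CDC6, which loads the replicative helicase, at 1.25 ± 0.13, CCNE2 at 0.98 ± 0.09, ORC6 at 0.95 ± 0.11 and GINS2 at 0.71 ± 0.08. Ribosome biogenesis genes rose in 16 of 21 cases (adjusted p = 3.73e-13; 18 adjusted over the list alone). Examples were the nucleolar helicase gene DDX21 (0.92 ± 0.05), NOLC1 (0.69 ± 0.06) and the RNA polymerase I subunit gene POLR1B (0.64 ± 0.07). Among 24 immediate early genes 10 rose and 3 fell (adjusted p = 0.000814, but adjusted p = 0.119 with an estimated correlation; 13 adjusted over the list alone). EGR3 (1.89 ± 0.10), KLF4 (1.14 ± 0.11) and MYC (0.85 ± 0.09) were among the increases, and CCN2 (−1.57 ± 0.36), DUSP4 (−0.68 ± 0.18) and DUSP6 (−0.52 ± 0.14) fell. Mitosis genes, which act later in the cycle, had 0 increases and 1 decrease among 22 (adjusted p = 0.974).

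The OHT-resistant line also responded to estradiol, with estrogen-induced targets among the genes that rose. TGM2 (3.65 ± 0.37), RAPGEFL1 (3.63 ± 0.32), TUBB2B (3.33 ± 0.42), GREB1 (3.09 ± 0.16), SMTNL2 (2.90 ± 0.44), the retinoic acid hydroxylase gene CYP26B1 (2.57 ± 0.40), the small heat-shock protein gene HSPB8 (2.48 ± 0.12) and DIO3 (2.32 ± 0.36) rose most. BAHCC1 (−2.58 ± 0.38), CCDC120 (−2.51 ± 0.52), GRHL3 (−2.21 ± 0.39), LINC02504 (−2.08 ± 0.60), IKZF2 (−2.06 ± 0.35), the matricellular gene CCN2 (−2.06 ± 0.36), ARID5B (−1.93 ± 0.10) and TRIM29 (−1.76 ± 0.43) fell most. Adjusted p-values were at most 0.0167 across the 16 genes. PGR rose by 1.27 ± 0.36 (adjusted p = 0.0151). ESR1 (−0.60 ± 0.09, adjusted p = 2.39e-05) and ERBB2 (−0.59 ± 0.08, adjusted p = 7.86e-06) fell on the probe sets used, but averaged over all their probe sets these values were 0.22 and 0.02. TFF1 (0.06 ± 0.08, adjusted p = 0.712) and EGFR (−0.29 ± 0.16, adjusted p = 0.273) were not called.

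Estradiol changed 2164 genes in this line, 1058 upwards and 1106 downwards. With median centring 1064 were higher and 825 lower, so the share of increases went from 48.9% to 56.3%, and with averaged probe sets 918 were higher and 728 lower. Of changes of at least 1 on the log2 scale, 151 were upwards and 99 downwards. Estrogen-induced targets rose in 25 of 35 cases and fell in 1, again AMIGO2 at −1.25 ± 0.10 (adjusted p = 4.73e-34; 28 adjusted over the list alone). Examples were the ubiquitin ligase gene SIAH2 at 2.26 ± 0.12 and EGR3 at 2.04 ± 0.10. Estrogen-repressed genes fell in 9 of 16 cases (adjusted p = 2.33e-09; 9 adjusted over the list alone). Examples were TP53INP1 (−1.36 ± 0.09), CCNG2 (−1.32 ± 0.12) and EFNA1 (−0.90 ± 0.12). Ribosome biogenesis genes rose in 15 of 21 cases (adjusted p = 4.53e-17; 18 adjusted over the list alone). Examples were DDX21 (0.63 ± 0.05), NOP16 (0.71 ± 0.07), POLR1B (0.68 ± 0.07) and NIP7 (1.07 ± 0.13). Among 17 epithelial junction genes 7 fell and 1, PKP3, rose by 0.31 ± 0.09 (adjusted p = 0.000141; 11 adjusted over the list alone). Examples were JUP, which encodes plakoglobin, at −0.53 ± 0.07, the tight-junction gene CGN at −0.91 ± 0.13, ESRP1 at −0.40 ± 0.06 and OCLN at −0.31 ± 0.05. Mitosis genes fell in 7 of 22 cases (adjusted p = 0.000114, but adjusted p = 0.151 with an estimated correlation; 9 adjusted over the list alone). Examples were the kinetochore gene CENPF at −0.38 ± 0.09 and CCNB2 at −0.28 ± 0.08. DNA replication genes rose in 5 of 28 cases (adjusted p = 0.0123, but adjusted p = 0.309 with an estimated correlation; 11 adjusted over the list alone). Examples were CDC6 (0.49 ± 0.13), RFC4 (0.25 ± 0.07), GINS2 (0.28 ± 0.08) and CDC25A (1.66 ± 0.48).

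In the ICI-resistant line the response was smaller, with some estrogen-induced targets higher and the interferon-stimulated and antigen presentation lists lower as a whole. HSPB8 (2.19 ± 0.12, or 4.57-fold), PDE6B (1.93 ± 0.46), RASGRP1 (1.86 ± 0.34), LINC02175 (1.83 ± 0.25), the neuropeptide Y receptor gene NPY1R (1.60 ± 0.24), GREB1 (1.43 ± 0.16), FAM133A (1.38 ± 0.27) and APOC1 (1.21 ± 0.27) rose most. C10orf67 (−1.84 ± 0.36), SAMD9L (−1.06 ± 0.22), ACYP1 (−0.78 ± 0.13), the peptide transporter gene TAP2 (−0.65 ± 0.12), OAS3 (−0.62 ± 0.14), PARP12 (−0.58 ± 0.12), HLA-J (−0.57 ± 0.12) and HLA-G (−0.56 ± 0.09) fell most. All 16 genes had an adjusted p of at most 0.0303. HLA-J and HLA-G were read from probe sets whose names end in _x_at, and 2 of the 4 HLA-G probe sets were called. Whether the signals of these and of the other HLA genes given here are separate from each other was not tested. Other named genes read from _x_at probe sets included APOC1, TUBB2B, GTF2IP20, LDHB, LINC02504, TOX3 and LILRB3. TFF1 rose by 1.08 ± 0.08 (adjusted p = 6.15e-10), from an intensity of 10470 to 20840, and ESR1 rose by 0.37 ± 0.09 (adjusted p = 0.0409), although 0 of its 5 probe sets were called in a test of each probe set. PGR (−0.03 ± 0.36, adjusted p = 0.994), ERBB2 (−0.27 ± 0.08, adjusted p = 0.107) and EGFR (−0.15 ± 0.16, adjusted p = 0.853) were not called.

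Here 209 genes passed the threshold, 164 higher and 45 lower, against 1802 genes at an unadjusted p under the same threshold. This count was the least stable of all. It was 35 (33 higher, 2 lower; 94.3% higher against 78.5%) with median centring. It was 118 (48 higher, 70 lower) when only the 8 arrays of this line were fitted and 63 to 363 when 1 of these arrays was left out. Estrogen-induced targets rose in 14 of 35 cases and fell in 0 (adjusted p = 2.03e-19; 16 adjusted over the list alone). Among them was the stress-response transcription factor gene XBP1 at 0.40 ± 0.06. The interferon-stimulated list had a median of −0.54, with 2 of 27 genes lower, TAP1 (−0.65 ± 0.14) and OAS3, and 9 called when adjusted over the list alone (adjusted p = 8.77e-17). Antigen presentation genes fell in 4 of 14 cases (adjusted p = 5.9e-11, with 8 called when adjusted over the list alone), namely HLA-G, HLA-B (−0.46 ± 0.08), TAP2 and TAP1. Of these, HLA-G rests on the _x_at probe set given above, and the separation of HLA-B from other HLA genes was also not tested. TAP1 is also in the interferon-stimulated list. Ribosome biogenesis genes rose in 4 of 21 cases (adjusted p = 1.03e-09; 10 adjusted over the list alone). Examples were DDX21 at 0.32 ± 0.05 and the fibrillarin gene FBL at 0.25 ± 0.05. Of 19 cholesterol synthesis genes 1 fell, the sterol carrier gene STARD4 at −0.51 ± 0.11 (adjusted p of the list = 0.000683; 3 adjusted over the list alone). Luminal epithelial markers rose in 4 of 19 cases, TFF1, XBP1, CA12 (0.37 ± 0.07) and ESR1 (adjusted p = 0.000704, but adjusted p = 0.117 with an estimated correlation; 4 adjusted over the list alone). Immediate early genes rose in 3 of 24 cases, KLF10 (0.49 ± 0.07), EGR3 (0.65 ± 0.10) and MYC (0.41 ± 0.09), with adjusted p = 0.00302, but adjusted p = 0.117 with an estimated correlation, and 6 adjusted over the list alone. EGR3 and MYC are also in the list of estrogen-induced targets, as are TFF1, XBP1 and CA12 of the luminal markers. Estrogen-repressed genes had 1 decrease in 16, EFNA1 at −0.48 ± 0.12 (adjusted p = 0.0118, but adjusted p = 0.0923 with an estimated correlation; 3 adjusted over the list alone). Epithelial junction genes had 0 in 17 (adjusted p = 0.0308, but adjusted p = 0.117 with an estimated correlation; 0 adjusted over the list alone).

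**Figure D2:**
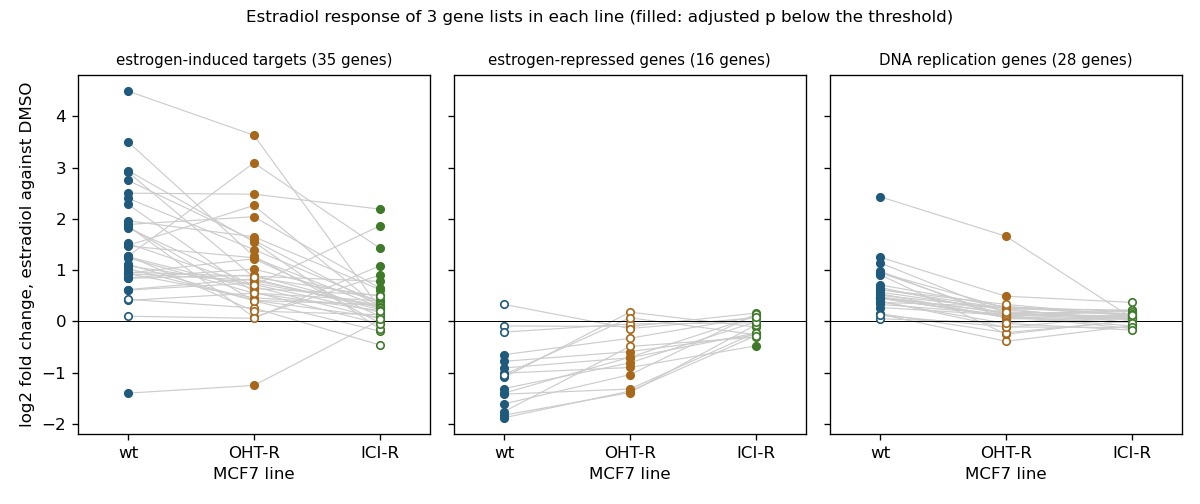
Log2 fold change of estradiol against DMSO (vertical) for each gene of 3 lists in the wt, OHT-resistant (OHT-R) and ICI-resistant (ICI-R) lines (horizontal), with a line joining the values of a gene; filled points passed the threshold and open points did not. Of 35 estrogen-induced targets, 32 rose in wt, 25 in OHT-resistant and 14 in ICI-resistant cells.

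Whether the lines responded differently was tested directly as a difference of responses. Against wt cells, the OHT-resistant line differed for 516 genes, 220 with a more positive and 296 with a more negative response. With median centring the counts were 373 and 150, so the more positive share moved from 42.6% to 71.3%, and the median over all genes moved from 0.03 to 0.13. DNA replication genes responded less in 13 of 28 cases and more in 0 (adjusted p = 1.01e-19; 20 adjusted over the list alone). Examples were the cyclin gene CCNE2 at −0.92 ± 0.13 and the ribonucleotide reductase gene RRM2 at −0.52 ± 0.10. Of 35 estrogen-induced targets 10 responded less and 2 more (adjusted p = 3.73e-08; 14 adjusted over the list alone): SLC7A5 (−1.71 ± 0.10), RET (−1.39 ± 0.17) and PGR (−2.23 ± 0.51) were among the former and GREB1 (1.82 ± 0.23) and SIAH2 (0.78 ± 0.16) were the latter. For GREB1 1 of its 2 probe sets was called in the opposite direction. SCNN1B (−3.54 ± 0.63), SCNN1G (−3.29 ± 0.73), both sodium channel subunit genes, and TFF2 (−3.32 ± 0.62) showed the most reduced responses, while PHLDB2 (3.44 ± 0.39) had the largest difference in the other direction.

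The ICI-resistant line differed from wt in the response of 1707 genes, 1041 more positive and 666 more negative, and any difference of dose enters here. With median centring these were 1464 and 406, which raised the more positive share from 61.0% to 78.3% and the median over all genes from 0.05 to 0.15. Estrogen-induced targets had a less positive response in 25 of 35 cases and a more positive one in 2, AMIGO2 (1.42 ± 0.14) and TFF1 (adjusted p = 6.03e-27; 30 adjusted over the list alone). AMIGO2 fell in wt cells (−1.40 ± 0.10) and was not called in the ICI-resistant line, so its difference comes from a decrease absent from the ICI-resistant calls. Of all called genes, SMTNL2 (−4.51 ± 0.62), RAPGEFL1 (−4.24 ± 0.46) and CHST8 (−4.19 ± 0.58) had the most negative differences, and PGR was at −3.52 ± 0.51. Estrogen-repressed genes were less repressed in 11 of 16 cases (adjusted p = 2.25e-10; 12 adjusted over the list alone). DNA replication genes responded less in 17 of 28 cases (adjusted p = 3.51e-17; 23 adjusted over the list alone). Ribosome biogenesis genes responded less in 7 of 21 cases and more in 1, NOB1 at 0.56 ± 0.15 (adjusted p = 1.89e-05; 11 adjusted over the list alone). TFF1 (0.98 ± 0.11, adjusted p = 3.13e-07) and ESR1 (1.32 ± 0.13, adjusted p = 3.65e-08) had more positive responses than in wt cells, and GREB1 did not differ by the test (0.16 ± 0.23, adjusted p = 0.747). For ESR1 1 of its 5 probe sets was called. Whether a signal as bright as that of TFF1 in wt cells could still rise is not known, so the size of its difference is uncertain. Antigen presentation genes responded more negatively in 4 of 14 cases (adjusted p = 0.000625; 4 adjusted over the list alone). Interferon-stimulated genes did so in 3 of 27 (adjusted p = 0.000625, but adjusted p = 0.0714 with an estimated correlation; 5 adjusted over the list alone).

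Between the resistant lines the responses of 788 genes differed, 485 more positive in the ICI-resistant line and 303 more negative, again with any difference of dose included. With averaged probe sets they were 438, 233 more positive and 205 more negative, and of differences of at least 1 on the log2 scale 49 were more positive and 79 more negative. RAPGEFL1 (−3.37 ± 0.46), TGM2 (−3.29 ± 0.52), TUBB2B (−3.05 ± 0.59) and CYP26B1 (−3.01 ± 0.57) responded less in the ICI-resistant line, and BAHCC1 (2.66 ± 0.54) was less repressed. Estrogen-induced targets had a less positive response there in 16 of 35 cases and a more positive one in 2 (adjusted p = 3.95e-18, with 22 called when adjusted over the list alone). The 2 were AMIGO2 (1.27 ± 0.14) and TFF1 (1.03 ± 0.11). AMIGO2 fell in the OHT-resistant line, as in wt cells, and was not called in the ICI-resistant line. For TFF1 the same doubt holds about its brightness in the OHT-resistant line. Ribosome biogenesis genes responded less in 7 of 21 (adjusted p = 2.72e-07; 11 adjusted over the list alone). DNA replication genes had 0 called differences in 28 between these lines (adjusted p = 0.275). The genes called in both the wt and OHT-resistant lines moved the same way in 1267 cases (625 up, 642 down) and oppositely in 25, where independent lists would share 102 up and 130 down. Over all genes tested, the responses in wt had r = 0.389 with those in the OHT-resistant and r = 0.106 with those in the ICI-resistant line. Among the 3141 genes called in wt, 85.5% had the same sign in the OHT-resistant line (r = 0.712 across genes, which are not independent replicates) and 60.8% in the ICI-resistant line (r = 0.27). The slope of the responses of these genes on those of wt cells was 0.459 in the OHT-resistant and 0.069 in the ICI-resistant line, and genes chosen for passing in wt carry wt estimates that are too large on average.

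Without estradiol, the OHT-resistant line had higher levels of cell-cycle and cholesterol synthesis genes than wt cells and lower levels of many luminal and estrogen-regulated genes. PEG10 (5.13 ± 0.12, or 35.1-fold), FGFBP2 (4.86 ± 0.35), CUX2 (4.37 ± 0.49), the long-chain acyl-CoA ligase gene ACSL4 (4.09 ± 0.26), the AMPK subunit gene PRKAA2 (4.07 ± 0.35), the lactate dehydrogenase gene LDHB (3.63 ± 0.28), HOPX (3.62 ± 0.52) and LNCATV (3.52 ± 0.42) were higher. MGP, encoding matrix Gla protein (−6.92 ± 0.17), GREB1 (−6.40 ± 0.16), VGLL1 (−5.71 ± 0.24), the kallikrein gene KLK11 (−5.68 ± 0.26), CLSTN2 (−5.48 ± 0.25), TOX3 (−5.21 ± 0.42), PKIB (−5.01 ± 0.09) and AZGP1 (−4.67 ± 0.34) were lower. Their adjusted p-values, with those of the 8 increases, were at most 2.26e-06. For TOX3 the value was 0.07 when dim probe sets were kept. PGR was lower (−1.82 ± 0.36, adjusted p = 0.000171) and ERBB2 slightly higher (0.32 ± 0.08, adjusted p = 0.00253; −0.01 as the mean of its probe sets). No call was made for TFF1 (0.07 ± 0.08, adjusted p = 0.537) and EGFR (0.17 ± 0.16, adjusted p = 0.464).

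Altogether 5371 genes differed, 2509 higher and 2862 lower in the OHT-resistant line. Median centring gave 1652 higher and 4220 lower (28.1% against 46.7% higher) and moved the median over all genes from −0.02 to −0.14, and relative to the median of all genes 2618 were higher and 2702 lower. The GAPDH 3′ minus 5′ log2 difference of the arrays, 0.318 in this line against 0.211 in wt, goes with every gene group here. All 22 mitosis genes were higher (adjusted p = 6.29e-17; 22 adjusted over the list alone). Examples were the topoisomerase gene TOP2A (1.27 ± 0.08), NDC80 (1.70 ± 0.11), CDK1 (1.43 ± 0.11) and CCNB2 (1.00 ± 0.08). DNA replication genes were higher in 25 of 28 cases (adjusted p = 1.07e-13; 25 adjusted over the list alone). Examples were POLE2 at 1.22 ± 0.07, the thymidylate synthase gene TYMS at 1.13 ± 0.07, the licensing factor gene CDT1 at 1.55 ± 0.11 and RRM2 at 0.86 ± 0.07. Cholesterol synthesis genes were higher in 18 of 19 cases and lower in 1, PMVK at −0.26 ± 0.09 (adjusted p = 6.73e-14; 19 adjusted over the list alone). Examples were the farnesyl diphosphate synthase gene FDPS at 0.99 ± 0.05, DHCR7 at 1.34 ± 0.08 and STARD4 at 1.68 ± 0.11. Luminal epithelial markers were lower in 12 of 19 cases and higher in 1, PRLR at 0.29 ± 0.08 (adjusted p = 7.02e-07; 13 adjusted over the list alone). Examples were KRT19 (−1.22 ± 0.05), XBP1 (−0.95 ± 0.06) and the trefoil peptide gene TFF3 (−3.61 ± 0.26). Epithelial junction genes were lower in 11 of 17 cases (adjusted p = 0.00188; 11 adjusted over the list alone). Examples were the claudin genes CLDN3 (−2.21 ± 0.07), CLDN4 (−1.25 ± 0.13) and CLDN7 (−0.74 ± 0.12). Estrogen-induced targets were lower in 18 of 35 cases and higher in 6 (adjusted p = 0.000734; 24 adjusted over the list alone). AMIGO2 was lower (−2.68 ± 0.10) and SLC7A5 higher (1.64 ± 0.07).

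Further lists differed less uniformly between these lines, beside the same GAPDH difference (0.318 against 0.211). Antigen presentation genes were higher in 7 of 14 cases (adjusted p = 0.00214, but adjusted p = 0.0512 with an estimated correlation; 7 adjusted over the list alone). Examples were HLA-G at 0.93 ± 0.09, on its _x_at probe set, and HLA-C at 0.70 ± 0.08. Immediate early genes were lower in 15 of 24 cases and higher in 3 (adjusted p = 0.00214, but adjusted p = 0.1 with an estimated correlation; 19 adjusted over the list alone). EGR1 stood at −1.39 ± 0.09 and KLF4 at −1.42 ± 0.11, against JUND at 0.67 ± 0.05, IER3 at 1.14 ± 0.10 and KLF6 at 0.56 ± 0.11. Wnt pathway genes were higher in 8 of 25 cases and lower in 2 (adjusted p = 0.0411, but adjusted p = 0.0858 with an estimated correlation; 10 adjusted over the list alone). Examples were the feedback regulator gene AXIN2 (2.30 ± 0.17), the ligand gene WNT5A (3.32 ± 0.35) and LEF1 (2.17 ± 0.37), while the receptor genes FZD2 (−0.53 ± 0.15) and FZD6 (−0.25 ± 0.08) were lower. The interferon-stimulated list did not stand apart (2 higher and 5 lower of 27, adjusted p = 0.868).

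The ICI-resistant line in DMSO differed from wt cells far more widely, with higher levels of most interferon-stimulated, antigen presentation and basal genes beside a lower level of ESR1. IFI44L (9.31 ± 0.38), SAMD9 (9.04 ± 0.46), IGFBP3, which encodes an insulin-like growth factor binding protein (8.23 ± 0.41), the basement membrane collagen gene COL4A5 (8.12 ± 0.40), IFI44 (7.90 ± 0.33), SELENOP (7.69 ± 0.33), TRIB2 (7.32 ± 0.38) and IFIT1 (7.29 ± 0.28) were higher. NPY1R (−8.89 ± 0.24), the GDNF receptor gene GFRA1 (−6.53 ± 0.24), TFF3 (−6.35 ± 0.26), GREB1 (−5.76 ± 0.16), DNAJC12 (−5.59 ± 0.27), PREX1 (−5.45 ± 0.12), PKIB (−5.19 ± 0.09) and SLC6A14 (−5.19 ± 0.30) were lower. None of these 16 genes had an adjusted p above 7.61e-15. PGR (−2.75 ± 0.36, adjusted p = 1.08e-07) and TFF1 (−2.67 ± 0.08, adjusted p = 2.61e-21) were lower and ERBB2 higher (1.05 ± 0.08, adjusted p = 4.79e-12). EGFR, the epidermal growth factor receptor gene, was higher on the probe set used (3.11 ± 0.16, adjusted p = 7.52e-16), as on 3 of its 6 probe sets, while 2 were called lower.

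These lines differed in 10145 genes, 3584 higher and 6561 lower, and the median over all genes was −0.36. That median was −0.21 for the values as deposited and −0.46 with median centring. Relative to the median of all genes 5085 were higher and 4423 lower. The arrays of the ICI-resistant line also differed as arrays. The 3′ minus 5′ log2 difference of the ACTB control probe sets was 0.599 ± 0.114 (SD, n = 8) against 2.17 ± 0.0959 (SD, n = 8) in wt. This difference goes with every gene group below. Interferon-stimulated genes, normally induced in antiviral defence, were higher in 26 of 27 cases (adjusted p = 1.28e-16; 27 adjusted over the list alone) with a median of 3.83, for instance IFITM1 (3.83 ± 0.12), OAS3 (4.42 ± 0.14) and ISG15 (4.77 ± 0.16), and only IFITM2 was lower (−0.39 ± 0.11). Antigen presentation genes were higher in 10 of 14 cases (adjusted p = 3.38e-06; 12 adjusted over the list alone). Examples were HLA-B at 3.84 ± 0.08, HLA-C at 3.38 ± 0.08 and TAP2 at 4.72 ± 0.12, while the class II genes HLA-DRB1 (−1.21 ± 0.16) and HLA-DPA1 (−2.32 ± 0.42) were lower. The separation of these HLA signals from each other was not tested. Basal markers were higher in 10 of 11 cases and lower in 1, SFN at −0.14 ± 0.06 (adjusted p = 4.54e-06; 11 adjusted over the list alone). Examples were the hyaluronan receptor gene CD44 (2.88 ± 0.06), the integrin gene ITGA6 (3.55 ± 0.20) and the basal keratin gene KRT5 (5.21 ± 0.30). Wnt pathway genes were higher in 14 of 25 cases and lower in 6 (adjusted p = 0.00183; 20 adjusted over the list alone). Examples were the Wnt antagonist gene DKK1 at 1.75 ± 0.06 and the receptor gene FZD6 at 1.42 ± 0.08. Unfolded protein response genes were higher in 10 of 18 cases and lower in 4 (adjusted p = 0.00324; 14 adjusted over the list alone). Examples were the endoplasmic reticulum chaperone genes PDIA4 (2.80 ± 0.07) and HSP90B1 (3.27 ± 0.15).

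Other lists were close to the threshold in this comparison, beside the same difference in the ACTB control (0.599 against 2.17). AHR targets were higher in 5 of 8 cases and lower in 1, CYP1A2 at −0.99 ± 0.14 (adjusted p = 0.0321, but adjusted p = 0.052 with an estimated correlation; 6 adjusted over the list alone). Examples were the cytochrome gene CYP1B1 (3.26 ± 0.08) and ALDH3A1 (4.08 ± 0.38). Cholesterol synthesis genes were higher in 10 of 19 cases and lower in 5 (adjusted p = 0.0315, but adjusted p = 0.052 with an estimated correlation; 15 adjusted over the list alone). DHCR7 was higher (1.36 ± 0.08) and the phosphomevalonate kinase gene PMVK lower (−2.01 ± 0.09). Epithelial junction genes were higher in 9 of 17 cases and lower in 4 (adjusted p = 0.0455, but adjusted p = 0.128 with an estimated correlation; 13 adjusted over the list alone). The E-cadherin gene CDH1 was at 1.01 ± 0.06 and CLDN3 at −1.29 ± 0.07, and the median of the list turned from 0.26 to −0.17 with median centring. Luminal epithelial markers were lower in 12 of 19 cases and higher in 4 without a call for the list (adjusted p = 0.0643; 16 adjusted over the list alone). Mesenchymal genes were higher in 7 of 14 cases and lower in 4 (adjusted p = 0.0624; 12 adjusted over the list alone). Among markers of other cell types, leukocyte markers had 0 higher and 1 lower of 5 (adjusted p = 0.777), fibroblast markers 1 higher and 4 lower of 5 (adjusted p = 0.955), and endothelial markers 1 higher and 3 lower of 5 (adjusted p = 0.982).

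**Figure D3:**
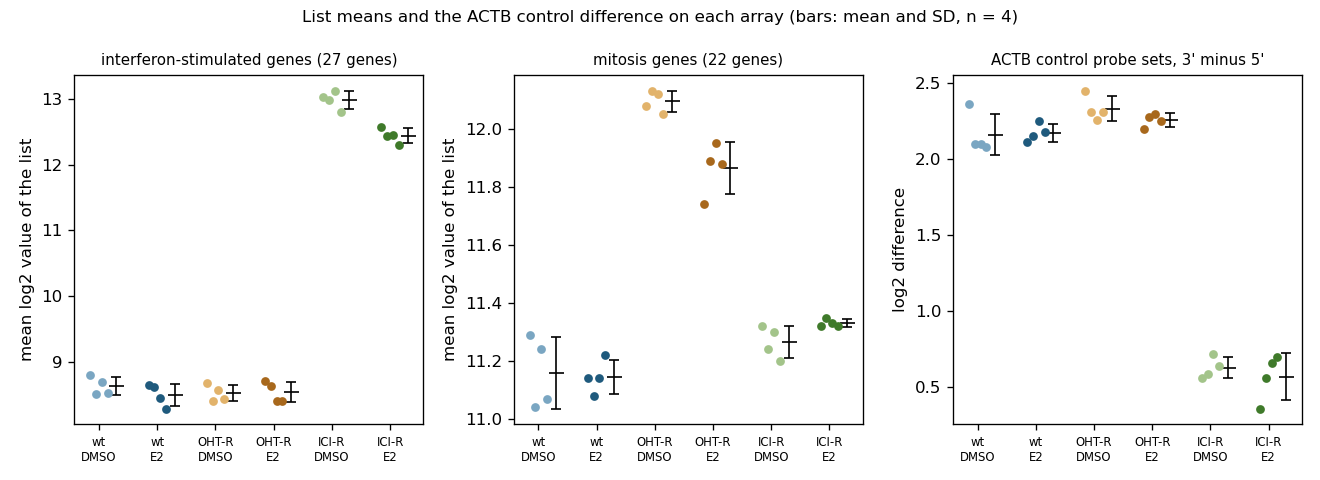
Mean log2 value of the interferon-stimulated and the mitosis genes, and the 3′ minus 5′ log2 difference of the ACTB control probe sets (vertical axes, which do not start at 0), on each of the 24 arrays (points) by line and treatment (horizontal), with the mean and SD of the 4 arrays of a group (bars). The interferon list averages 8.64 in wt DMSO, 12.98 in ICI-resistant DMSO and 12.44 in ICI-resistant cells with estradiol.

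Compared with the OHT-resistant line, the ICI-resistant line had higher levels of interferon-stimulated genes and of most basal markers. IFI44L (9.64 ± 0.38), IGFBP3 (8.87 ± 0.41), IFIT1 (8.63 ± 0.28), COL4A5 (8.44 ± 0.40), SAMD9 (8.25 ± 0.46), the netrin gene NTN4 (8.20 ± 0.45), IFI44 (7.73 ± 0.33) and IFI6 (7.45 ± 0.29) were higher. FGFBP2 (−6.13 ± 0.35), the receptor kinase gene ERBB4 (−6.10 ± 0.28), PEG10 (−5.80 ± 0.12), PREX1 (−5.77 ± 0.12), NPY1R (−5.65 ± 0.24), BFSP2 (−5.37 ± 0.29), ELAPOR1 (−5.08 ± 0.17) and FAM181B (−4.82 ± 0.30) were lower. The highest adjusted p among the 16 genes was 2.7e-14. ESR1 (−3.72 ± 0.09, adjusted p = 8.4e-23), TFF1 (−2.74 ± 0.08, adjusted p = 1.07e-21) and PGR (−0.94 ± 0.36, adjusted p = 0.0228) were lower, and GREB1 (0.65 ± 0.16, adjusted p = 0.000902) and ERBB2 (0.73 ± 0.08, adjusted p = 8.58e-09) were higher. Of the 5 ESR1 probe sets 1 was called lower and 0 higher. EGFR was higher on the probe set used (2.94 ± 0.16, adjusted p = 2.62e-15), while 3 of its 6 probe sets were called in the opposite direction.

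Here 10196 genes differed, 3695 higher and 6501 lower, with a median over all genes of −0.35 (−0.25 as deposited); relative to that median 5164 were higher and 4435 lower. The ACTB control difference was 2.30 ± 0.0727 (SD, n = 8) in the OHT-resistant line, against 0.599 in the ICI-resistant one, beside every list that follows. Interferon-stimulated genes were higher in 26 of 27 cases and lower in 1, IFITM2 at −0.35 ± 0.11 (adjusted p = 2.7e-16; 27 adjusted over the list alone). Antigen presentation genes were higher in 9 of 14 with HLA-DRB1 (−1.70 ± 0.16) and HLA-DPA1 (−1.77 ± 0.42) lower (adjusted p = 9.17e-05; 11 adjusted over the list alone). Basal markers were higher in 8 of 11 cases and lower in 1, SFN at −1.11 ± 0.06 (adjusted p = 0.000142; 9 adjusted over the list alone). Epithelial junction genes were higher in 11 of 17 cases and lower in 2 (adjusted p = 0.000324; 13 adjusted over the list alone), with CLDN4 at 2.87 ± 0.13 but CRB3 at −0.79 ± 0.17 and JUP at −0.19 ± 0.07, and mesenchymal genes in 7 of 14 with MMP2 (−0.99 ± 0.40) lower (adjusted p = 0.00556; 8 adjusted over the list alone). Examples were the fibronectin gene FN1 at 3.04 ± 0.09 and SNAI2 at 3.53 ± 0.45. AHR targets were higher in 6 of 8 cases and lower in 2, CYP1A2 at −0.52 ± 0.14 and TIPARP at −0.30 ± 0.11 (adjusted p = 0.00556; 8 adjusted over the list alone). DNA replication genes were lower in 22 of 28 cases and higher in 1 (adjusted p = 0.00107, but adjusted p = 0.122 with an estimated correlation; 23 adjusted over the list alone). CDT1 was at −2.03 ± 0.11, and the value of MCM7, the higher one at 0.38 ± 0.08, turned to −0.13 with median centring. Mitosis genes were lower in 17 of 22 cases and higher in 1 (adjusted p = 0.00556, but adjusted p = 0.23 with an estimated correlation; 18 adjusted over the list alone). The survivin gene BIRC5 was at −2.96 ± 0.11, and CENPF, the higher one at 0.26 ± 0.09, was at −0.44 as the mean of its probe sets. Unfolded protein response genes were higher in 10 of 18 cases and lower in 6 (adjusted p = 0.0102, but adjusted p = 0.0858 with an estimated correlation; 16 adjusted over the list alone). Immediate early genes were higher in 14 of 24 cases and lower in 6 (adjusted p = 0.0327, but adjusted p = 0.234 with an estimated correlation; 20 adjusted over the list alone). Examples were KLF6 at 2.26 ± 0.11 and DUSP6 at 2.54 ± 0.14.

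Both resistant lines were compared with the same wt arrays, so their changes share chance values. Among genes called in both, 2743 moved the same way (1060 higher, 1683 lower), among them PKIB and GREB1, both lower in each line, and 1499 moved oppositely. Independent lists of these lengths would share 612 higher and 1278 lower genes. The log2 fold changes had a correlation of 0.211 across genes, which are not independent replicates, against 0.498 (0.478 to 0.517) in 50 simulations of unchanged lines against the same wt arrays, where 0 genes were called in both. The covariance was 0.158 against 0.0381 simulated, a difference of 0.12 beyond the shared chance values. Anything peculiar to the wt cells or their arrays as a whole also enters this difference. It therefore cannot be read as an effect shared by the resistant lines. When each resistant line was set against a different pair of wt arrays, 1983 to 2236 genes moved the same way and the correlation was 0.124 to 0.178.

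Several lists of interest in hormone resistance were called in none of the 9 comparisons. Receptors and ligands of the ERBB and IGF families had 9 higher and 8 lower of 21 in ICI-resistant against wt cells (adjusted p = 0.367), and 8 higher and 6 lower in OHT-resistant against wt cells (adjusted p = 0.998). Nuclear receptors had 6 higher and 8 lower of 23 (adjusted p = 0.717), receptor coregulators 4 higher and 11 lower of 20 (adjusted p = 0.713), and retinoid genes 5 higher and 3 lower of 11 (adjusted p = 0.425) in ICI-resistant against wt cells. Apoptosis regulators had 5 higher and 8 lower of 19 (adjusted p = 0.713) and DNA methylation enzymes 3 higher and 6 lower of 11 (adjusted p = 0.883) in the same comparison.

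The control probe sets differed between the lines, most for the ICI-resistant arrays, as given beside the gene groups. The larger excess of 3′ over 5′ ACTB signal was on the wt (2.17) and OHT-resistant (2.30) arrays, and the smaller on the ICI-resistant ones (0.599). Among DMSO arrays the ACTB 3′ minus 5′ difference was lower by −1.53 in ICI-resistant than in wt arrays and by −1.71 than in OHT-resistant arrays, each with an exact two-sided permutation p of 0.0286, the smallest that 70 splits can give, and 0.0686 after adjustment over 12 tests. The GAPDH difference was 0.0588 in the ICI-resistant, 0.211 in the wt and 0.318 in the OHT-resistant arrays. Among DMSO arrays it was higher by 0.1 in OHT-resistant than in wt arrays and lower by −0.14 and −0.24 in ICI-resistant than in wt and OHT-resistant arrays, with the same p-values (0.0286, and 0.0686 adjusted). The ACTB difference of OHT-resistant and wt arrays was 0.17 (exact two-sided permutation p = 0.114). All 8 ICI-resistant arrays shared the low ACTB difference, so array and line cannot be told apart for it. Between estradiol and DMSO arrays of one line, the ACTB difference changed by 0.01 in wt, −0.08 in OHT-resistant and −0.06 in ICI-resistant cells (exact two-sided permutation p of 0.914, 0.143 and 0.629).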

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

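The tests chosen only after the result was seen were those of the array scaling for both patterns that name it, and that of leukocytes; the other tests were set down first. Among 66 groups of 4 arrays, 4 held an array far from the others, where chance gives about 1 in 20 groups. The median intensity of wt estradiol replicate 2 was 232 against 210 to 212 on the other arrays of its group. The ACTB 3′ minus 5′ difference of wt DMSO replicate 1 was 2.36 against 2.08 to 2.1. The ESR1 log2 level of wt estradiol replicate 1 was 13.88 against 13.49 to 13.55. The TFF1 log2 level of ICI-resistant DMSO replicate 3 was 13.25 against 13.6 to 13.64.

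The estradiol responses of the OHT-resistant and wt lines differed, by the test of the difference itself, for 516 genes. The highest of the other splits gave 56 (1 of 100 splits, the real one, was as large, the smallest share that 100 splits can give). Responses were more positive in the OHT-resistant line for PHLDB2 (3.44), GTF2IP20 (3.12), CCDC68 (2.88), GIPC3 (2.64), LRRN3 (2.63), PCDH17 (2.52). The others were LILRB3 (2.46), MRGPRF-AS1 (2.32) and GREB1 (1.82, with 1 of its 2 probe sets called in the opposite direction). More negative responses were those of SCNN1B (−3.54), TFF2 (−3.32), SCNN1G (−3.29), MYOM1 (−3.12), UNC5A (−3.02), ANXA10 (−2.88). So were CCDC120 (−2.75), PGLYRP2 (−2.65), PGR (−2.23), SLC7A5 (−1.71), RET (−1.39), OLFM1 (−1.08), CA12 (−1.01), CCNE2 (−0.92), ORC6 (−0.86), RRM2 (−0.52) and MCM7 (−0.51), as log2 differences. Lists that differed were the estrogen-induced targets (adjusted p = 3.73e-08), estrogen-repressed genes (adjusted p = 0.000693), DNA replication genes (adjusted p = 1.01e-19) and cholesterol synthesis genes (adjusted p = 0.00124). The calls of mitosis genes (adjusted p = 0.000207) and epithelial junction genes (adjusted p = 0.0114) ended with an estimated correlation (adjusted p = 0.162 and adjusted p = 0.0855).

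Between the ICI-resistant and wt lines the responses of 1707 genes differed. The highest of the other splits gave 412 (1 of 100 splits, the real one, was as large, the smallest share that 100 splits can give). A difference of dose was not tested, since the labels give none in nM for the ICI-resistant line. More positive in the ICI-resistant line were MMP13 (2.85), GTF2IP20 (2.82), WNT7B (2.61), ZNF792 (2.58), GRHL3 (2.43), PDE6B (2.41), SOX2 (2.37), CHRM1 (2.31). Smaller ones were TGFB2 (1.75), TP53INP1 (1.60), BIK (1.5), ESR1 (1.32), CCNG2 (1.21), TFF1 (0.98), DUSP4 (0.97) and ERBB2 (0.51). The call of CHRM1 was near the threshold (limma adjusted p = 0.0498), and its probe set was not called in a test of each probe set. More negative were SMTNL2 (−4.51), RAPGEFL1 (−4.24), CHST8 (−4.19), SCNN1B (−3.73), PGR (−3.52), FCGR2B (−3.26), KCNQ1 (−3.20), OSGIN1 (−3.15). Then came RET (−3.09), IGFBP4 (−2.45), SLC7A5 (−2.33), CA12 (−2.04). Still smaller were EGR3 (−1.24), ORC6 (−1.04), KLF4 (−1), CCNE2 (−0.93), NOLC1 (−0.66), DDX21 (−0.60), TYMS (−0.55), RFC4 (−0.54), NOP58 (−0.50), NOP16 (−0.41) and JUND (−0.27). The lists were estrogen-induced targets (adjusted p = 6.03e-27), estrogen-repressed genes (adjusted p = 2.25e-10), antigen presentation genes (adjusted p = 0.000625), DNA replication genes (adjusted p = 3.51e-17), ribosome biogenesis genes (adjusted p = 1.89e-05) and cholesterol synthesis genes (adjusted p = 0.0172). The calls of interferon-stimulated genes (adjusted p = 0.000625) and immediate early genes (adjusted p = 0.0382) ended with an estimated correlation (adjusted p = 0.0714 and adjusted p = 0.369).

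Between the resistant lines 788 genes differed in response. The highest of the other splits gave 122 (1 of 100 splits, the real one, was as large, the smallest share that 100 splits can give). BAHCC1 (2.66), TRPM4 (2.37), PDE6B (2.20), IKZF2 (2.10), CCN2 (2.07), GRHL3 (2.06), LNX1 (1.96) and ARID5B (1.93) responded more positively in the ICI-resistant line. TGFB2 (1.18), CCNG2 (1.10), TP53INP1 (1.08), TFF1 (1.03), ESR1 (0.97, but −0.05 with averaged probe sets) and PNRC1 (0.80) did so too. For PDE6B (limma adjusted p = 0.0455) 0 of its 2 probe sets were called in a test of each probe set. RAPGEFL1 (−3.37), TGM2 (−3.29), TUBB2B (−3.05), CYP26B1 (−3.01), HOXC5 (−2.70), SMTNL2 (−2.58), NR5A2 (−2.55) and C22orf42 (−2.40) responded more negatively. Also more negative were SIAH2 (−2), RET (−1.70), GREB1 (−1.66), EGR3 (−1.39), CA12 (−1.03), NOP16 (−0.58), NOP58 (−0.54), NOLC1 (−0.40) and DDX21 (−0.30). The lists were estrogen-induced targets (adjusted p = 3.95e-18), estrogen-repressed genes (adjusted p = 2.32e-06), interferon-stimulated genes (adjusted p = 4.2e-06) and ribosome biogenesis genes (adjusted p = 2.72e-07). The calls of mitosis (adjusted p = 1.03e-05), antigen presentation (adjusted p = 0.00284), epithelial junction (adjusted p = 0.0257) and unfolded protein response genes (adjusted p = 0.0293) ended with an estimated correlation (adjusted p = 0.0912, 0.0757, 0.107 and 0.127).

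Interferon-stimulated genes were high in the ICI-resistant line and lower there after estradiol, a list mean of 12.98 in DMSO and 12.44 with estradiol. To examine probe sets that follow the arrays and not the gene, further kept probe sets were counted, and 12 of 13, or 92.3%, were higher in the ICI-resistant line. They belong to 10 genes. A probe set high in the ICI-resistant arrays alone passes the filter, so this count cannot decide the question. Against leukocytes among the cells, leukocyte markers had a median of −0.84, with intensities in wt and ICI-resistant DMSO arrays of 398 and 204 for CD79A and 279 and 143 for CD3E. Against scaling, the median after estradiol was still −0.45 in the scaling that brought it closest to 0. As a test of chance, 1 of 35 splits, the real one, gave a mean difference as large (−0.54, highest other 0.43). No smaller share is possible with 35 splits, so the splits alone do not exclude chance for the decrease after estradiol. After estradiol 2 of 27 genes were called one by one. A biological difference of this line stays open, and its source was not tested.

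The median gene was lower in ICI-resistant than in wt cells by −0.36. As deposited, the median intensity over all probe sets went the other way, 247.8 on the ICI-resistant and 204.2 on the wt DMSO arrays. As a test of the 3′ to 5′ difference of the arrays, the brightest minus the dimmest probe set of a gene changed by −0.13 at the median (95% bootstrap interval −0.15 to −0.09 over 4016 genes), against 0.02 for the OHT-resistant line. The probe sets were ranked by brightness, and their position in the transcript was not used. Scaling brought the median no closer to 0 than −0.21. Both explanations cannot be told apart from a biological difference, since all 8 arrays of the line share the feature and no scale is known to be right. A lower level of many genes in this line could therefore be technical in part.

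TFF1 had no called estradiol response in the wt and OHT-resistant lines, where it was among the brightest genes, and rose in the ICI-resistant line from a lower level. Of the genes as bright as TFF1 in both groups compared, 0 changed by 0.5 or more in any comparison. Genes chosen for being bright in both groups have little room to differ, so this count decides nothing. The rule set down first read a count of 0 as support for a signal at the top of the scale, and this reading was dropped after the value was seen. A signal at the top of the scale and a lack of response in these lines cannot be told apart, so the differences of responses given for TFF1 (0.98 and 1.03) are uncertain in size.

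Other splits of the 8 arrays compared were counted for each pair of groups, and in each case 1 of 35 splits, the real one, called as many genes. That is the smallest share that 35 splits can give, so the splits alone do not exclude chance. The other splits mix both groups, and any true difference widens their spread and lowers their counts. The real and highest other counts for estradiol were 3141 and 4 in wt, 2164 and 42 in OHT-resistant and 209 and 48 in ICI-resistant cells. For the lines they were 5371 and 10 for OHT-resistant against wt, 10145 and 1 for ICI-resistant against wt, and 10196 and 3 for ICI-resistant against OHT-resistant cells.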

How the results depend on the processing

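The batch and code letter terms and the removal of 4 or 2 arrays were tests chosen only after the results were seen; the other alternatives were planned. Of 486 values of named genes, 291 kept their direction and their side of the threshold in every alternative run on them (51 had no value under the stricter filter, and the code letter bears on comparisons with wt alone), 191 lost the call in at least 1, and 10 reversed. For 144 values the requirement of a log2 fold change of at least 1 ended the call by construction. Averaging the probe sets of a gene reversed ESR1 (0.22), ERBB2 (0.02) and BUB1 (0.11) for estradiol in the OHT-resistant line, ERBB2 in OHT-resistant against wt cells (−0.01), ESR1 in the difference of the resistant lines' responses (−0.05), JUND (0.24) and CENPF (−0.44) in ICI-resistant against OHT-resistant cells, and MVK in the difference of the ICI-resistant and wt responses (0.08), since other probe sets of these genes enter. Without a filter TOX3 in OHT-resistant against wt cells was 0.07. MCM7 in ICI-resistant against OHT-resistant cells was −0.04 as deposited and −0.13 with median centring. Among the reversed values only CENPF (limma adjusted p = 0.00157) was called in its new direction.

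The number of genes changed by estradiol in the ICI-resistant line (209) was 80 for values as deposited, 35 with median centring, 123 with averaged probe sets, 82 without the trend, 118 with its own arrays alone and 314 with the batch term. Leaving out 1 array gave 63 to 363: 72 without DMSO replicate 3, and 115, 63, 110 and 363 without estradiol replicates 1, 2, 3 and 4. The cause was not tested. The difference between the responses of the resistant lines was 438 genes with averaged probe sets. Requiring a log2 fold change of at least 1 left, by construction, 486, 250 and 13 genes for estradiol in wt, OHT-resistant and ICI-resistant cells, 1174, 5077 and 5095 for OHT-resistant against wt, ICI-resistant against wt and ICI-resistant against OHT-resistant cells, and 109, 318 and 128 for the differences of responses (OHT-resistant and wt, ICI-resistant and wt, ICI-resistant and OHT-resistant), and 406 shared changes. Without 1 array the other counts ranged over 2729 to 3010 and 1811 to 2084 for estradiol in wt and OHT-resistant cells, 4904 to 5131, 9659 to 9824 and 9743 to 9997 for the lines, and 379 to 531, 1421 to 1767 and 616 to 766 for the differences of responses, in the same orders. Of 69 list calls, 44 held with an estimated correlation, 67 with the replicate block, 68 with the batch term and 65 without the 4 arrays.

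The replicate numbers were not taken to pair the arrays: estradiol and DMSO arrays of 1 line with the same number had residual correlations of −0.04 to 0.13 across genes, and 10 of 24 arrays correlated best with their own number. These were all 8 arrays of wt, 1 of 8 of the OHT-resistant and 1 of 8 of the ICI-resistant line, so in wt the numbers go with the residuals and pairing stays open there. With the replicate block the counts were 3048, 2085 and 149 for estradiol, 4664, 10285 and 9935 for the lines, and 411, 1586 and 667 for the differences of responses. After the data were seen, 4 arrays were found to deviate together: DMSO replicate 1 and estradiol replicate 1 of wt, and DMSO replicate 4 and estradiol replicate 1 of the OHT-resistant line (r of 0.1 to 0.13 across genes). The batch term gave 3424, 2404, 5579, 10173, 10312, 654, 1923 and 945 genes for the other comparisons, and leaving these arrays out gave 2815, 1813, 272, 4956, 9951, 10099, 493, 1646 and 682. The design text gives the wt arrays numbered 1 another code letter. A term for it gave 3221, 5274, 10004, 557 and 1764 genes for the 5 comparisons with wt arrays, and leaving these 2 arrays out gave 2682, 5062, 9840, 470 and 1500. Genes whose signal is near the background are the least certain, since the added 21 and the filter act on them.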

Other observations

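The lists and the rule for naming their members were fixed first, and which of the lists without a camera call to describe, but no test, was chosen after the values were seen. Growth factor receptors and their ligands differed one by one. In the ICI-resistant line, beside a higher level of IGFBP3 (8.23 ± 0.41), the receptor gene ERBB4 was lower than in wt cells (−4.97 ± 0.28, adjusted p = 3.22e-15), as was IGFBP5 (−1.25 ± 0.07, adjusted p = 1.78e-15). The OHT-resistant line had less of the insulin receptor substrate gene IRS1 (−1.13 ± 0.07, adjusted p = 5.96e-14), ERBB3 (−0.66 ± 0.06, adjusted p = 3.51e-10) and the EGFR ligand gene TGFA (−2.75 ± 0.28, adjusted p = 4.45e-09), and more IRS2 (1.12 ± 0.08, adjusted p = 1.05e-11). Among luminal transcription factors, FOXA1, which opens chromatin for the estrogen receptor, was lower in ICI-resistant than in wt cells (−2.79 ± 0.10, adjusted p = 5.93e-20). Mesenchymal genes in the same comparison included FN1 (4.51 ± 0.09), LGALS1 (1.58 ± 0.10) and TGFBI (3.32 ± 0.35) as higher and CAV2 (−1.07 ± 0.09) as lower. The ACTB 3′ minus 5′ difference of the arrays was 0.599 in this line and 2.17 in wt.

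Receptors other than ESR1 differed too. In the ICI-resistant line the orphan receptor gene NR2F1 (5.38 ± 0.48, adjusted p = 7.94e-11) and the thyroid hormone receptor gene THRB (2.51 ± 0.16, adjusted p = 2.77e-14) were higher and ESRRA was lower (−0.91 ± 0.07, adjusted p = 5.96e-12) than in wt cells. The OHT-resistant line had more of the glucocorticoid receptor gene NR3C1 (1.51 ± 0.12, adjusted p = 3.42e-11) and less PPARG (−2.51 ± 0.25, adjusted p = 2.69e-09). Estradiol in wt cells raised the corepressor gene NRIP1 (1.47 ± 0.10, adjusted p = 2.18e-12) and the retinoid genes DHRS3 (1.45 ± 0.27, adjusted p = 0.000195), CYP26B1 (1.59 ± 0.40, adjusted p = 0.00428) and RARA (0.84 ± 0.17, adjusted p = 0.000351), while the retinoid list as a whole was not called (adjusted p = 0.48). In the OHT-resistant line the methyl-CpG binding protein gene MBD2 was lower (−1.37 ± 0.08, adjusted p = 4.45e-14) and the DNA methyltransferase gene DNMT1 higher (0.68 ± 0.07, adjusted p = 1.55e-08) than in wt cells. Apoptosis genes in ICI-resistant against wt cells went both ways, with the death receptor gene FAS at 2.69 ± 0.17 and the proapoptotic genes BID at −1.43 ± 0.09 and BIK at −1.86 ± 0.15.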
